A study of Arabidopsis thaliana with 10 samples.

How the data were processed

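The series holds RNA sequencing of whole Arabidopsis thaliana seedlings, 10 days old, in 5 genotypes with 2 libraries each. The labels name plants carrying 35S:IBH1-GFP (here the IBH1 overexpressor), plants with a T-DNA insertion in IBH1 (ibh1 mutant), plants carrying 35S:IBL1-GFP (IBL1 overexpressor), plants with a T-DNA insertion in IBL1 (ibl1 mutant) and the wild type Col. The labels number 2 libraries per genotype, while a protocol text speaks of more repeats; the 10 numbered libraries are taken as the design, and nothing states whether they came from separate cultures, so p-values may measure technical spread only.

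Per the labels, the RNA was selected for poly(A) and made into libraries with an Illumina kit. Per the submitters' processing notes, reads were called with CASAVA 1.8.2 and processed with TopHat 1.4.1 and Cuffdiff against TAIR10; the Cuffdiff version, its scaling between groups, its gene models and whether it used strand are not given in the sources used here. The authors deposited 4 tables, 1 per line against Col, each with 34047 genes. Per the file headers, each table holds an FPKM value for the line and an FPKM value for Col (sequenced fragments scaled for transcript length and library size, 1 value per group of 2 libraries), a log2 fold change, a test statistic, a p-value, a q-value and a test status. No value per library entered the work, so no spread between replicates could be computed, no count test could be refitted and no library could be left out. The depth per library is unknown, because low FPKM values show no steps of whole reads, and no interval that needs a depth is given.

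What the columns hold was checked on the values. The deposited log2 fold change is Col over line, so its sign was turned and every fold change here is line over Col. The deposited p-value equals the two-sided normal p of the deposited statistic to within 2.81e-06, and the authors' q-value equals a Benjamini-Hochberg adjustment over the genes of status OK to within 2.39e-06. The standard error of a log2 fold change, printed after ±, was therefore taken as the fold change divided by the statistic. Where a group is listed at 0 the files give no usable fold change, and none is printed. Col values were the same in the 4 tables except for at most 3 genes. Gene starts were shifted to count from 1. Of the 34047 gene IDs, 31294 (91.9%) are in the reference annotation used for symbols (TAIR10.1, whose chromosome lengths hold every position of the files); coordinates are those of the files. IBL1 has no symbol in that annotation and was taken as AT4G30410 (bHLH159) from general knowledge of the family.

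A gene was called where the authors' q-value was below 0.05 among genes of status OK, in either direction. The median log2 fold change over genes with FPKM of at least 1 in both groups was 0.01 in the IBH1 overexpressor, 0.01 in the ibh1 mutant, 0.12 in the IBL1 overexpressor and -0.07 in the ibl1 mutant. Because of these shifts the calls were also made after subtracting that median, with the same standard errors and Benjamini-Hochberg adjustment (centred calls), and changes in the IBL1 overexpressor are given beside its shift.

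Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives unless said otherwise. They cover the targets IBH1 and IBL1, the PRE family, growth-promoting bHLH of the HBI1/BEE/ACE/CIB clade, growth-restraining HLH/bHLH, phytochrome-interacting factors, brassinosteroid biosynthesis, inactivation and signalling, expansins, xyloglucan endotransglucosylase/hydrolases, SAUR genes, Aux/IAA and GH3 genes, gibberellin metabolism and response, light harvesting and Rubisco small subunit, pathogen and jasmonate defence, flavonoid and anthocyanin biosynthesis, iron deficiency, circadian clock, root hair markers, root endodermis, stele, cap and epidermis markers, seed storage, reference genes, chloroplast-encoded genes, mitochondrion-encoded genes and ribosomal proteins by annotation text. The last list was meant for cytosolic ribosomal proteins, but the annotation text also brought in plastid-type proteins. In all, 6 members (PRE2, PRE4, ACE1, ACE3, FIT and SAND) were left out because the annotation lists other names for their IDs and not these, which does not show that the IDs are wrong. Lists with at least 3 tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed statistic (competitive, two-sided, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 22 lists tested in a comparison. A correlation between genes cannot be estimated from group values, so a preset correlation of 0.05 was an alternative. A statistic grows with expression as well as with change, so 2 further alternatives used the log2 fold change with a pseudocount of 0.1 or 1 as the gene's value, and another set the list's median log2 fold change against 10000 random lists of the same size matched on mean FPKM in 20 bins.

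Overlaps between comparisons were counted among genes tested in both, per direction. All comparisons use the same Col libraries, which shares chance between them. Each overlap is therefore given beside the count for independent lists and beside the mean of 200 simulations of unchanged groups set against the same Col values. Covariances and correlations of log2 fold changes are given beside the simulated ones. The simulations, covariances and correlations covered only genes with FPKM of at least 1 in all groups compared and standard errors below 1. These are fewer than the genes over which overlaps were counted. In the simulations Col carried a fixed share of the smaller of the 2 squared errors of a gene. They drew only on errors implied by the authors' statistic. They therefore do not bound what Col libraries that differed in other ways would share between comparisons. A difference between 2 lines was tested as the difference of their log2 fold changes over the root of the summed squared errors, which counts the Col error on both sides and is conservative. An alternative cut the summed squared errors by a fixed share, the same for every gene, as if Col and line carried equal errors. It is called dropping the Col error here, though Col's own error was not estimated.

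The tests were run on simulated data for the real genes and errors. Among 200 genes changed in the IBH1 overexpressor, the centred test recovered 60% of those changed 2-fold and 86% of those changed 4-fold over 19136 genes; 7.01% of its calls were false. The corresponding shares were 70% and 91% in the ibh1 mutant over 19390 genes, 70% and 88% in the IBL1 overexpressor over 19441 genes and 64% and 90% in the ibl1 mutant over 19201 genes. The difference test recovered 39% and 73% between the overexpressors over 18915 genes and 48% and 78% between the mutants over 18973 genes, with 0 false calls in either. With the Col error dropped, 8.77% and 8.19% of its calls were false. On data simulated for the IBH1 overexpressor over 20216 genes, cameraPR and the random lists each called the 1 lowered list and 0 of the others. The genes were simulated as independent, so this single run does not show false calls among genes that vary together. A covariance of 0.0451 put in for the overexpressors over 18488 genes was found as 0.0462, and 0.0468 put in for the mutants over 18580 genes as 0.0481.

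The genes named are IBH1 and IBL1; per comparison the 8 largest rises and 8 largest falls among called genes with FPKM of at least 1 in both groups; per list up to 4 called members of smallest q-value, or 2 of highest FPKM where none was called; 5 genes called in opposite directions in the mutant and the overexpressor of the same gene; 5 called in the same direction in both overexpressors and in both mutants; and 5 with the largest difference between the overexpressors. Only part of the genes this rule allows are printed, and any gene named outside it is said to have been chosen after its values were seen. Other alternatives were a q-value threshold of 0.01, a change of at least 2-fold, a minimum FPKM of 1, keeping the 6 members and a centred statistic for the lists; the last pair was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.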

Results

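IBH1 is an atypical basic helix-loop-helix protein that lacks a DNA-binding basic region and restrains cell elongation in the brassinosteroid response, and IBL1 is its close homologue. Transcripts of whole seedlings, 10 days old, were measured by RNA sequencing in lines that overexpressed either gene from the 35S promoter, in insertion mutants of either gene and in the wild type Col, with 2 libraries per genotype. The values are the authors' FPKM, fold changes and q-values, 1 value per genotype; no spread between replicate libraries can be shown, and the depth per library is unknown. Log2 fold changes are line over Col, and the figure after ± is the standard error implied by the authors' statistic.

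Both overexpressors carried far more of their transcript than Col, and both mutants kept part of theirs. IBH1 (AT2G43060, chromosome 2, 17909185 to 17910082, TAIR10) was at 5148 FPKM in the IBH1 overexpressor against 22.2 FPKM in Col in the authors' deposited table, a 232-fold rise (log2 7.86 ± 0.18, q listed as 0). It fell to 6.91 FPKM in the ibh1 mutant, 31.2% of Col (log2 -1.68 ± 0.33, authors' q 5.63e-05). The IBL1 overexpressor had 20.3 FPKM and the ibl1 mutant 17.4 FPKM (authors' q 0.79 and 0.519). IBL1 (AT4G30410, chromosome 4, 14871109 to 14872176) rose 26.1-fold in the IBL1 overexpressor, from 7.70 to 201 FPKM (log2 4.71 ± 0.30), and fell to 1.87 FPKM in the ibl1 mutant (log2 -2.04 ± 0.59, authors' q 0.0148). IBL1 also fell in the IBH1 overexpressor, to 1.84 FPKM (log2 -2.07 ± 0.69, authors' q 0.0363), and was at 7.27 FPKM in the ibh1 mutant (authors' q 0.951). Reads from the transgene and from the native gene are counted together in an overexpressor.

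**Figure D1:**
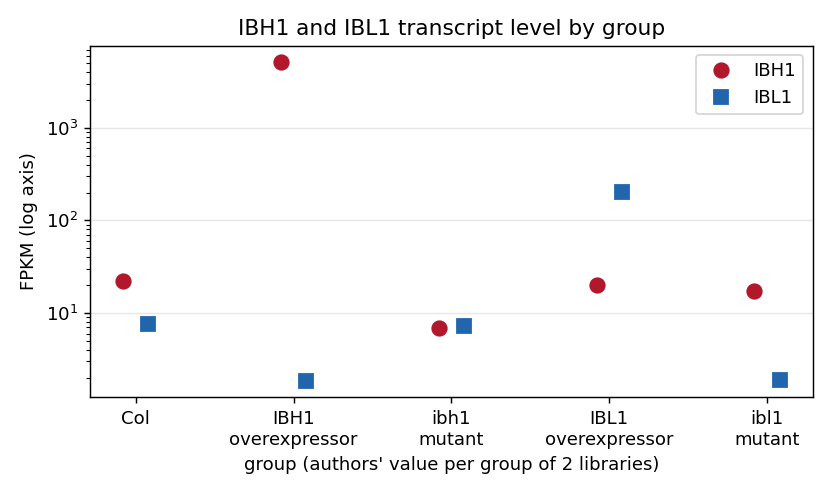
FPKM of IBH1 (circles) and IBL1 (squares) in each of the 5 genotypes on a log axis, with the authors' single value per group of 2 libraries as each point. IBH1 peaks at 5148 FPKM in its overexpressor, IBL1 peaks at 201 FPKM in its own, and IBL1 is at 1.84 FPKM in the IBH1 overexpressor and 1.87 FPKM in the ibl1 mutant.

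The first comparison concerns excess IBH1. As IBL1 was at 1.84 FPKM in this line, against 1.87 FPKM in the ibl1 mutant, it also holds lower IBL1. Changes from excess IBH1 and from less IBL1 cannot be told apart here. EXPA8 (AT2G40610, chromosome 2, 16948863 to 16950557), an expansin that loosens cell walls, fell most among genes at 1 FPKM or more in both groups, from 41.0 to 1.61 FPKM (log2 -4.67 ± 0.57). GASA6 (AT1G74670, chromosome 1, 28053286 to 28054149), a gibberellin-induced gene of cell elongation, fell from 305 to 18.4 FPKM (log2 -4.05 ± 0.25). ASN1 (AT3G47340), an asparagine synthetase of dark and starved tissue, fell by 2.84 ± 0.19 on the log2 scale, and MSRB6 (AT4G04840) by 3.35 ± 0.61. The floral MADS-box gene SEP3 (AT1G24260, chromosome 1, 8593642 to 8596098) rose from 5.49 to 45.0 FPKM (log2 3.03 ± 0.29), the defence gene LURP1 (AT2G14560) by 2.70 ± 0.28 and the defensin PDF1.3 (AT2G26010) by 2.68 ± 0.48. By the authors' q-values, 1659 of 20694 tested genes were called, 791 higher and 868 lower. A change of at least 2-fold was seen in 194 of the higher and 180 of the lower ones.

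Of 8 growth-restraining HLH/bHLH genes, 5 fell, 0 rose and 3 were not called (6 lower adjusted over the list alone), with a median log2 of -1.47. AIF1 (AT3G05800) had -3.21 ± 0.79, PAR1 (AT2G42870) -2.75 ± 0.49, AIF4 (AT1G09250) -1.46 ± 0.28 and AIF3 (AT3G17100) -0.97 ± 0.11. Among 9 growth-promoting bHLH genes of the HBI1/BEE/ACE/CIB clade, BEE2 fell (-0.69 ± 0.14) and CIB4 rose (0.72 ± 0.19), the same counts adjusted over the list alone. None of 4 PRE genes was called (PRE3 0.14 ± 0.36). PIF4 (AT2G43010, chromosome 2, 17886427 to 17889050), a light-signalling bHLH that promotes elongation, fell by 1.77 ± 0.20 and PIF5 by 0.22 ± 0.07, while the other 3 PIF genes were not called (1 higher and 2 lower adjusted over the list alone). Of 10 brassinosteroid biosynthesis genes 4 fell (5 adjusted over the list alone). CPD (AT5G05690) was at -0.65 ± 0.09, DWF4 at -1.05 ± 0.27, BR6OX2 at -0.92 ± 0.28 and DWF1 at -0.34 ± 0.07. Of 9 signalling genes 4 fell (4 adjusted over the list alone, where 1 was higher), among them BKI1 (-0.97 ± 0.29) and the receptor gene BRI1 (-0.48 ± 0.10).

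Of 22 expansins 9 fell and 0 rose (11 lower adjusted over the list alone), with EXPA1 at -1.36 ± 0.10 and EXPA3 at -1.24 ± 0.18. Of 24 xyloglucan endotransglucosylase/hydrolases 8 fell and 1 rose, the same counts adjusted over the list alone. XTH8 had -1.81 ± 0.21, XTH4 -0.91 ± 0.08 and XTH31 0.59 ± 0.11. Of 14 Aux/IAA and GH3 genes 4 fell and 1 rose (5 and 1 adjusted over the list alone), from IAA7 at -1.46 ± 0.11 to GH3.3 at 0.73 ± 0.22. Of 13 gibberellin genes 5 fell (6 lower and 1 higher adjusted over the list alone). Of 20 SAUR genes SAUR16 alone was called (-1.18 ± 0.29; 1 adjusted over the list alone), although the list's median was -1.08. All 15 light-harvesting genes fell and the 4 Rubisco small subunit genes were not called (15 lower adjusted over the list alone), with LHCB2.3 at -1.26 ± 0.08 and LHCB1.2 at -1.08 ± 0.10. Near-identical copies such as LHCB1.1 to LHCB1.3 share reads, so single members are uncertain. Of 14 defence genes 6 rose and 1 fell (6 and 2 adjusted over the list alone), with WRKY53 at 1.22 ± 0.35, PR1 (AT2G14610) at 1.23 ± 0.25 and PR2 (AT3G57260) at 1.00 ± 0.19.

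By cameraPR, 11 of 22 lists were called in the IBH1 overexpressor. The lower ones were light harvesting (adjusted p 6.9e-43), expansins (1.35e-12), growth-restraining HLH/bHLH (8.37e-08), gibberellin (8.35e-07), xyloglucan enzymes (0.000379), brassinosteroid biosynthesis (0.000589), Aux/IAA and GH3 (0.00061), and SAUR (0.0158). Ribosomal proteins (9 lower of 134, 8 adjusted over the list alone) and reference genes (2 lower of 8, 2 adjusted over the list alone) were lower as well (0.00061 each). Defence was higher (0.033). With the log2 fold change (pseudocount 0.1) as value only growth-restraining HLH/bHLH (adjusted p 0.00046), expansins (0.0107) and SAUR (8.13e-05) stayed called. The other 8 lists had adjusted p between 0.148 and 0.949. A pseudocount of 1 kept 5 of the 11 calls. A correlation of 0.05 ended the calls of SAUR (0.0874), defence (0.0945) and ribosomal proteins (0.0877). Set against random matched lists, the reference genes, led by UBQ10 (-0.32 ± 0.02) and ACT7 (-0.42 ± 0.07), had an adjusted p of 0.861. The uncalled lists held few calls, among them 2 of 6 iron genes (BHLH39 0.73 ± 0.24), 2 of 10 clock genes (PRR7 -0.70 ± 0.17, TOC1 0.46 ± 0.14), 1 of 7 root hair markers (RHS19 0.59 ± 0.19) and 1 of 9 other root markers (SHR -0.81 ± 0.22). Of the organelle-encoded genes, 6 of 107 in the chloroplast were higher and 4 lower and 0 of 79 in the mitochondrion were called, and no flavonoid gene was called (CHS -0.04 ± 0.08).

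The second comparison asks what the loss of IBH1 transcript changes. The defence gene PR2 (AT3G57260, chromosome 3, 21188517 to 21189859), a salicylate-induced glucanase, fell from 18.6 to 1.12 FPKM (log2 -4.06 ± 0.57) and PR1 (AT2G14610, chromosome 2, 6241704 to 6242463), a marker of salicylate response, from 19.3 to 0.454 FPKM (log2 -5.41 ± 1.07). PCR1 (AT1G14880), a cadmium resistance gene chosen after its values were seen, had -6.17 ± 1.25. The lipase gene PLA2A (AT2G26560) fell by 2.21 ± 0.31, the tyrosine aminotransferase TAT3 by 1.84 ± 0.39, DIN11 by 1.77 ± 0.45 and PR5 by 0.89 ± 0.21. The jacalin-related lectin JAL23 (AT2G39330) rose from 5.27 to 17.2 FPKM (log2 1.70 ± 0.28) and the jasmonate-induced storage protein VSP2 by 0.96 ± 0.15. The authors' q-values gave 707 calls among 20967 tested genes, 280 higher and 427 lower, of which 35 and 56 changed at least 2-fold.

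In the ibh1 mutant PIF4 fell by 1.00 ± 0.16 and PIF5 by 0.26 ± 0.07 (2 of 5 PIF genes, 2 adjusted over the list alone). CPD fell by 0.35 ± 0.10 (1 of 10 biosynthesis genes, 1 adjusted over the list alone), and the receptor homologue BRL1 rose by 0.99 ± 0.29 (1 of 9 signalling genes, 1 adjusted over the list alone). Of 22 expansins 2 fell (2 adjusted over the list alone), EXPA16 (-1.22 ± 0.28) and EXPA3 (-0.52 ± 0.15), and of 24 xyloglucan enzymes XTH9 alone (-0.39 ± 0.10; 1 adjusted over the list alone). None of 8 growth-restraining, 9 growth-promoting, 3 PRE and 20 SAUR genes was called (1 growth-promoting gene higher adjusted over the list alone). AIF3 had -0.11 ± 0.10 and HBI1 -0.05 ± 0.12. Of 14 Aux/IAA and GH3 genes 3 fell (7 adjusted over the list alone), with GH3.6 at -0.72 ± 0.14 and GH3.5 at -0.76 ± 0.18. GASA14 fell (-0.69 ± 0.10) and GASA6 rose (0.45 ± 0.10) among 13 gibberellin genes (1 lower and 2 higher adjusted over the list alone). Of the 19 light-harvesting and Rubisco genes 10 fell (14 adjusted over the list alone), LHCB1.2 by 0.76 ± 0.12.

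CameraPR called 7 of 22 lists in the ibh1 mutant. Light harvesting (adjusted p 4.17e-16), ribosomal proteins (18 lower of 135, 2 higher and 27 lower adjusted over the list alone, 1.47e-10), Aux/IAA and GH3 (2.42e-05), PIF genes (0.02) and defence (1 higher and 3 lower of 12, 2 and 5 adjusted over the list alone, 0.0325) lay lower. Root endodermis, stele, cap and epidermis markers (2 higher of 11, 4 adjusted over the list alone, 0.02) and root hair markers (1 higher of 7, 1 adjusted over the list alone, 0.0295) lay higher, with CASP1 at 0.67 ± 0.17, PHO1 at 0.48 ± 0.12 and RHS19 at 0.74 ± 0.18. With the log2 fold change (pseudocount 0.1) as value only defence stayed called (adjusted p 0.0427), and the other 6 lists had adjusted p between 0.0804 and 0.9. A pseudocount of 1 kept 1 of the 7 calls. A correlation of 0.05 ended the calls of defence (0.0943), root hair (0.0612) and other root markers (0.0563). Random matched lists gave PIF genes 0.137, root hair markers 0.0854 and ribosomal proteins 0.0504. The remaining lists were not called. Within them the iron reductase gene FRO2 (0.70 ± 0.16) and the clock gene LHY (0.27 ± 0.06) rose, and PRR7 (-0.51 ± 0.16), UBQ10 (-0.26 ± 0.02), 5 of 109 chloroplast-encoded and 2 of 79 mitochondrion-encoded genes fell, and 0 of 9 flavonoid genes were called.

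The third comparison concerns excess IBL1. Among genes at 1 FPKM or more in both groups PIF4 fell most, from 33.2 to 5.53 FPKM (log2 -2.58 ± 0.23). Others that fell were the chlorophyll synthesis gene PORA (AT5G54190, -2.21 ± 0.45), AT2G33830, a dormancy and auxin-associated gene (-2.12 ± 0.13), and SEN1 (AT4G35770), a gene of dark-induced senescence (-2.09 ± 0.12). The senescence and defence genes SAG13 (AT2G29350, 34.5 against 2.69 FPKM, log2 3.68 ± 0.40), LURP1 (3.20 ± 0.27), the thioredoxin TH8 (AT1G69880, 3.09 ± 0.66) and PR1 (115 against 19.3 FPKM, log2 2.57 ± 0.22) rose. By the authors' q-values, 2990 of 21480 tested genes were called, 2221 higher and 769 lower, with 441 and 110 changed at least 2-fold. The median over expressed genes was shifted by 0.12 here. After centring 2473 genes were called, 1188 higher and 1285 lower, and the share of higher calls went from 74.3% to 48.0%. Fold changes of single genes below include that shift.

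The growth-promoting bHLH genes HBI1 (AT2G18300) and BEE2 fell in the IBL1 overexpressor. HBI1 had -0.86 ± 0.13 and BEE2 -0.96 ± 0.16 (2 of 9 clade members lower, 2 adjusted over the list alone), and none of 4 PRE genes was called. Of 5 PIF genes 3 fell (3 adjusted over the list alone), with PIF5 at -0.56 ± 0.06 and PIF1 at -0.49 ± 0.18. PAR1 (-0.94 ± 0.28) and AIF3 (-0.44 ± 0.10) were the 2 of 8 growth-restraining genes called (2 adjusted over the list alone). CPD (-0.79 ± 0.08), DET2 (-0.69 ± 0.22) and DWF1 (-0.21 ± 0.06) fell among 10 biosynthesis genes (3 adjusted over the list alone). Among 9 signalling genes BES1 fell (-0.26 ± 0.04) and BAK1 rose (0.37 ± 0.11; 1 lower and 2 higher adjusted over the list alone), the latter call being lost after centring. Of 22 expansins 4 fell and 1 rose (4 and 2 adjusted over the list alone), with EXPA8 at -1.39 ± 0.20 and EXLA1 at 1.06 ± 0.19. Of 24 xyloglucan enzymes 7 rose and 1 fell (8 and 1 adjusted over the list alone), led by the touch-induced TCH4 (AT5G57560, 2.02 ± 0.16) and XTH23 (1.59 ± 0.26). Of 14 Aux/IAA and GH3 genes 3 fell (3 adjusted over the list alone), among them IAA29 (-1.99 ± 0.70) and GH3.6 (-0.65 ± 0.13). Of 14 gibberellin genes 4 fell (4 lower and 1 higher adjusted over the list alone), among them GASA6 (-1.60 ± 0.12) and GASA14 (-0.44 ± 0.08), and of 20 SAUR genes SAUR16 fell (-1.08 ± 0.27; 1 adjusted over the list alone).

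All 15 light-harvesting genes fell again (15 adjusted over the list alone), LHCB2.2 by 1.74 ± 0.07 and LHCB1.2 by 1.72 ± 0.09, with a median over the 19 members of -1.12 relative to the shift. Of 15 defence genes 11 rose and 0 fell (13 adjusted over the list alone), among them WRKY33 (1.01 ± 0.16) and LOX2 (0.50 ± 0.07). Of 10 flavonoid genes 6 rose (7 adjusted over the list alone), with chalcone synthase CHS at 0.81 ± 0.07, FLS1 at 0.86 ± 0.12, CHI at 0.75 ± 0.17 and F3H at 0.54 ± 0.13.

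CameraPR called 13 of 22 lists in the IBL1 overexpressor. Lower were light harvesting (adjusted p 4.91e-130), PIF genes (1.02e-05), chloroplast-encoded genes (1 higher and 13 lower of 110, 1 and 12 adjusted over the list alone, 8.94e-05), SAUR (0.00178), brassinosteroid biosynthesis (0.00229), gibberellin (0.0026), Aux/IAA and GH3 (0.0132), growth-restraining HLH/bHLH (0.0212), the HBI1 clade (0.0359) and mitochondrion-encoded genes (2 lower of 84, 2 adjusted over the list alone, 0.0428). Higher were defence (2.81e-11), flavonoid genes (1.2e-05) and xyloglucan enzymes (0.0204). With the log2 fold change (pseudocount 0.1) as value only light harvesting (9.79e-05), SAUR (5.85e-06) and defence (0.00314) stayed called in their direction. Chloroplast-encoded genes turned higher (0.0259), and the other 9 lists had adjusted p between 0.362 and 0.887. A pseudocount of 1 kept 3 of the 13 calls. Random matched lists ended the calls of xyloglucan enzymes (0.737) and gibberellin genes (0.479), and centring those of the HBI1 clade (0.0504) and mitochondrion-encoded genes (0.452). A correlation of 0.05 ended those of the HBI1 clade (0.0807), growth-restraining genes (0.0503), xyloglucan enzymes (0.0897), Aux/IAA and GH3 (0.0503) and mitochondrion-encoded genes (0.286). Within uncalled lists the iron genes FRO2 (0.58 ± 0.15) and IRT1 (0.35 ± 0.10), the clock gene TOC1 (0.53 ± 0.13), the root genes CASP1 (0.75 ± 0.16) and WER (1.86 ± 0.68) and the reference gene GAPC1 (0.43 ± 0.06) rose, and PRR7 fell (-1.60 ± 0.19). The calls of IRT1 and WER were lost after centring. None of 7 root hair markers was called, and 4 of 135 ribosomal protein genes were higher and 4 lower (0 and 2 adjusted over the list alone).

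The fourth comparison concerns the loss of IBL1. PR1 rose from 19.3 to 193 FPKM (log2 3.32 ± 0.21), and LURP1 (2.49 ± 0.28), the lipid transfer protein gene LTP4 (AT5G59310, 2.33 ± 0.53), SAG13 (2.02 ± 0.42) and JAL23 (2.01 ± 0.27) rose with it. ASN1 fell from 44.5 to 10.5 FPKM (log2 -2.09 ± 0.17), the phosphate starvation gene SPX3 (AT2G45130) by 2.21 ± 0.59 and PORA by 2.12 ± 0.45. By the authors' q-values, 1130 of 20732 tested genes were called, 217 higher and 913 lower, with 47 and 90 changed at least 2-fold. The share of higher calls was 19.2%, and after centring 802 genes were called, 312 higher and 490 lower, a share of 38.9%.

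PIF4 fell again, by 1.65 ± 0.18, with PIF5 (-0.58 ± 0.09; 2 of 5 PIF genes, 2 adjusted over the list alone). PAR1 (-1.26 ± 0.31) and AIF3 (-0.34 ± 0.10) fell among 8 growth-restraining genes (2 adjusted over the list alone), and CPD (-0.56 ± 0.09) and DWF1 (-0.20 ± 0.06) among 10 biosynthesis genes (3 adjusted over the list alone). Centring ended the calls of AIF3 and DWF1. Of 22 expansins EXPA16 fell (-0.86 ± 0.27, a call lost after centring) and EXPA2 was listed at 0 against 2.04 FPKM in Col (authors' q 0.044; 2 lower and 1 higher adjusted over the list alone). Of 23 xyloglucan enzymes XTH4 fell (-0.24 ± 0.08, lost after centring; 1 adjusted over the list alone). Of 14 Aux/IAA and GH3 genes 4 fell (5 lower and 1 higher adjusted over the list alone; GH3.6 -0.73 ± 0.14), and GASA14 fell among 13 gibberellin genes (-0.65 ± 0.08; 2 adjusted over the list alone). The 15 light-harvesting genes fell in this line too (15 lower and 1 higher of 19 adjusted over the list alone), LHCB1.2 by 1.27 ± 0.09 and LHCA1 by 0.89 ± 0.08. Of 15 defence genes 6 rose and 1 fell, the same counts adjusted over the list alone, with VSP2 at 1.45 ± 0.13, VSP1 at 1.09 ± 0.23 and LOX2 at 0.44 ± 0.07.

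CameraPR called 7 of 22 lists in the ibl1 mutant. Light harvesting (adjusted p 6.59e-54), ribosomal proteins (30 lower of 135, 45 adjusted over the list alone, 1.98e-11), reference genes (1 lower of 8, 3 adjusted over the list alone, 9.87e-05), PIF genes (0.000202) and brassinosteroid biosynthesis (0.00471) lay lower. Defence (1.58e-11) and chloroplast-encoded genes (3 higher and 4 lower of 109, the same adjusted over the list alone, 0.00472) lay higher. With the log2 fold change (pseudocount 0.1) as value only chloroplast-encoded genes stayed called (0.00332), and the other 6 lists had adjusted p between 0.0595 and 0.991. A pseudocount of 1 kept 3 of the 7 calls. A correlation of 0.05 ended the chloroplast call (0.204). Random matched lists ended those of PIF genes (0.233), biosynthesis (0.0858) and reference genes (0.687). Within uncalled lists the iron transporter gene IRT1 (33.4 against 66.6 FPKM), the clock genes GI (-1.37 ± 0.25) and PRR7 (-1.29 ± 0.19) and 5 of 73 mitochondrion-encoded genes fell, and LHY rose (0.21 ± 0.06). No HBI1 clade, PRE, SAUR, brassinosteroid signalling, flavonoid or root marker gene was called (1 clade gene higher, 1 signalling gene and 3 root hair markers lower adjusted over the list alone). Brassinosteroid inactivation had 2 members, too few for the list test, and neither was called in any line (SOB7 -0.12 ± 0.37 in the IBH1 overexpressor). No seed storage gene was tested.

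**Figure D2:**
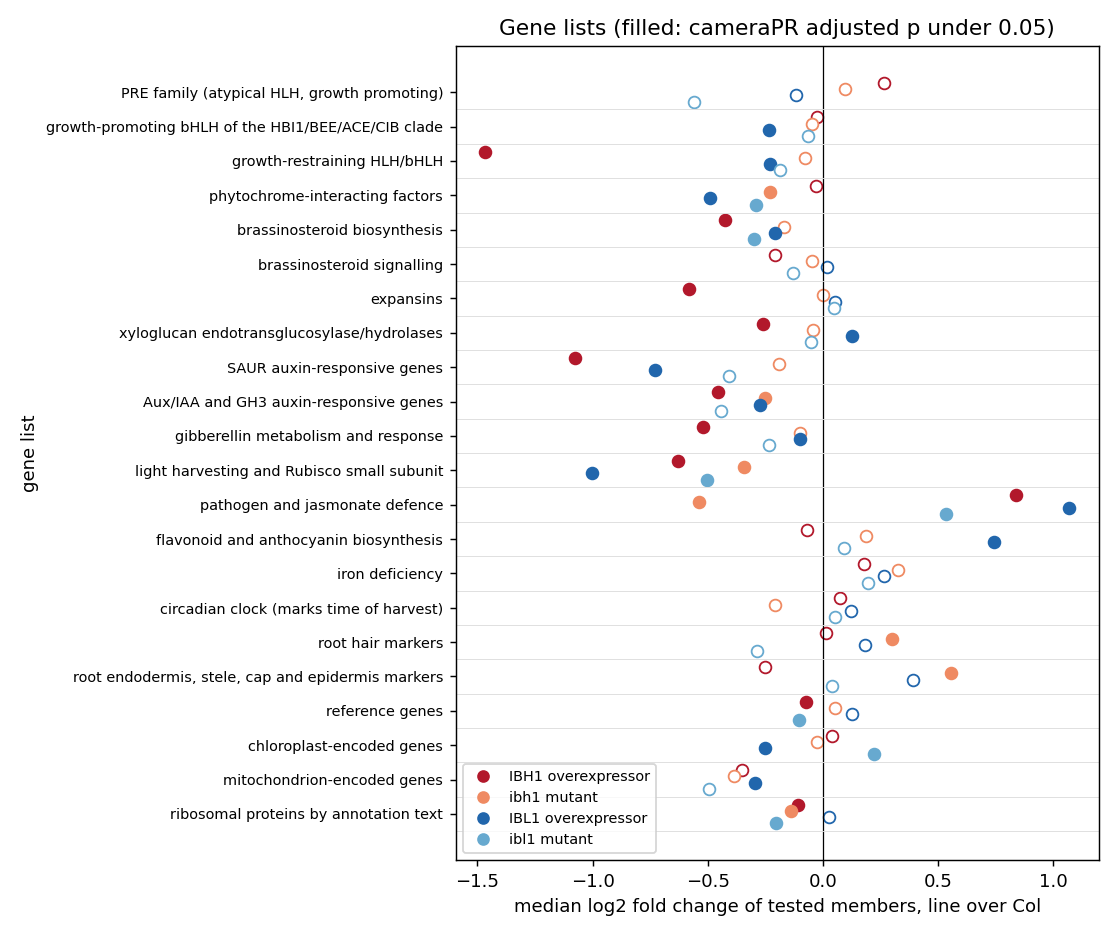
Median log2 fold change over Col (horizontal axis) of the tested members of 22 gene lists (vertical axis) in the 4 lines (colours), filled where the cameraPR adjusted p was below 0.05. Light harvesting lies lower in all 4 lines (-0.63 in the IBH1 overexpressor), growth-restraining HLH/bHLH and expansins lie at -1.47 and -0.58 in the IBH1 overexpressor, and defence lies at -0.54 in the ibh1 mutant and at 1.07 in the IBL1 overexpressor.

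The overexpressors shared many calls. IRT3 (AT1G60960, chromosome 1, 22445310 to 22447214), a zinc and iron transporter gene, rose by 4.95 ± 0.73 in the IBH1 overexpressor and 5.03 ± 0.72 in the IBL1 overexpressor, from 0.551 FPKM in Col. The flagellin-induced receptor kinase gene FRK1 (AT2G19190) rose by 3.46 ± 1.03 and 3.55 ± 1.02. The serine carboxypeptidase-like gene scpl23 (AT2G24010) fell by 2.82 ± 0.85 and 3.34 ± 0.90, and PIF4, EXPA8 and GASA6 fell in both. Among 20400 genes tested in both, 649 were called in the same direction (379 higher and 270 lower, with 83.2 and 32.7 for independent lists) and 102 in opposite directions. Independent lists would give 116 and 122. Unchanged groups sharing the Col values gave 6.04 and 0 on average, simulated over a smaller set of 18488 genes. The covariance of log2 fold changes over 18488 genes was 0.0933 against 0.0451 simulated, while the Pearson correlation was 0.460 against 0.449 and the Spearman correlation 0.401 against 0.415. The Col libraries cannot be split and the simulations do not bound their share, so how much of the excess comes from the shared control cannot be told. Sharing was not particular to the overexpressors. The IBL1 overexpressor and the ibh1 mutant shared 412 calls in the same direction and 28 in opposite directions. For the IBH1 overexpressor and the ibl1 mutant these counts were 337 and 52.

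**Figure D3:**
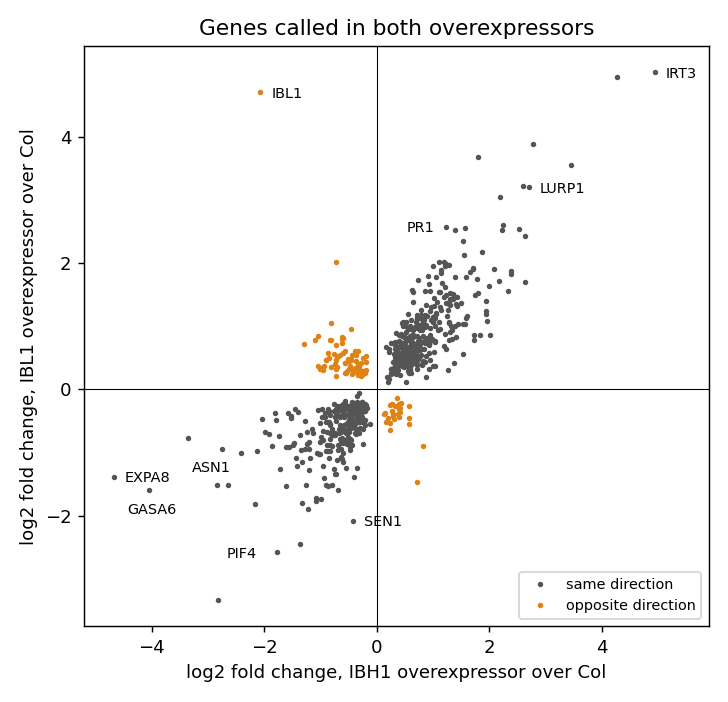
Log2 fold change over Col of the 745 genes called in both overexpressors and not listed at 0, IBH1 overexpressor on the horizontal and IBL1 overexpressor on the vertical axis. The 643 genes in grey changed in the same direction and the 102 in orange in opposite directions, IBL1 among the latter.

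The difference test separated the overexpressors at 1096 of 20005 genes, with the IBH1 overexpressor above at 279 and below at 817; after centring both, 1020 genes passed, 509 above and 511 below. Besides IBH1 and IBL1, AT3G01345 (chromosome 3, 129138 to 130749) was at 162 FPKM in the IBH1 overexpressor and 0.245 in Col (log2 9.37 ± 1.02), against 2.35 ± 1.12 in the IBL1 overexpressor. PRP40C (AT3G19840, chromosome 3, 6891129 to 6897227), a splicing factor gene, fell by 4.86 ± 0.76 in the IBL1 overexpressor and had 0.23 ± 0.22 in the IBH1 overexpressor. RD20 (AT2G33380), a drought-induced caleosin gene, differed by -4.46 ± 1.15, having -2.97 ± 1.08 in the IBH1 overexpressor (not called) and 1.49 ± 0.39 in the IBL1 overexpressor.

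The mutants also shared calls. IRT3 rose in both (4.44 ± 0.73 in ibh1, 4.42 ± 0.73 in ibl1), as did JAL23 (1.70 ± 0.28 and 2.01 ± 0.27), and scpl23 (-5.41 ± 1.64 and -4.07 ± 1.11), the defensin-like gene AT3G59930 (-1.83 ± 0.57 and -2.33 ± 0.70) and the meiotic gene HEI10 (AT1G53490, -1.69 ± 0.36 and -2.91 ± 0.53) fell in both. Of 20336 genes tested in both, 310 were called in the same direction (51 higher and 259 lower, with 2.90 and 19.1 for independent lists) and 13 in opposite directions, against 22.0 and 16.9 for independent lists and 1.95 and 0 for unchanged groups sharing Col. The covariance was 0.0801 against 0.0468 simulated, the Pearson correlation 0.560 against 0.462 and the Spearman correlation 0.542 against 0.429. How much of the excess comes from the shared control cannot be told. The difference test found 93 of 19969 genes, 62 higher and 31 lower in ibh1 than in ibl1 (27 and 44 of 71 after centring). PR1 and PR2 were lower in ibh1 than in ibl1 (differences -8.73 and -4.04), and ASN1 (1.68 ± 0.21) and IRT1 (1.33 ± 0.18), both chosen after their values were seen, were higher in ibh1.

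**Figure D4:**
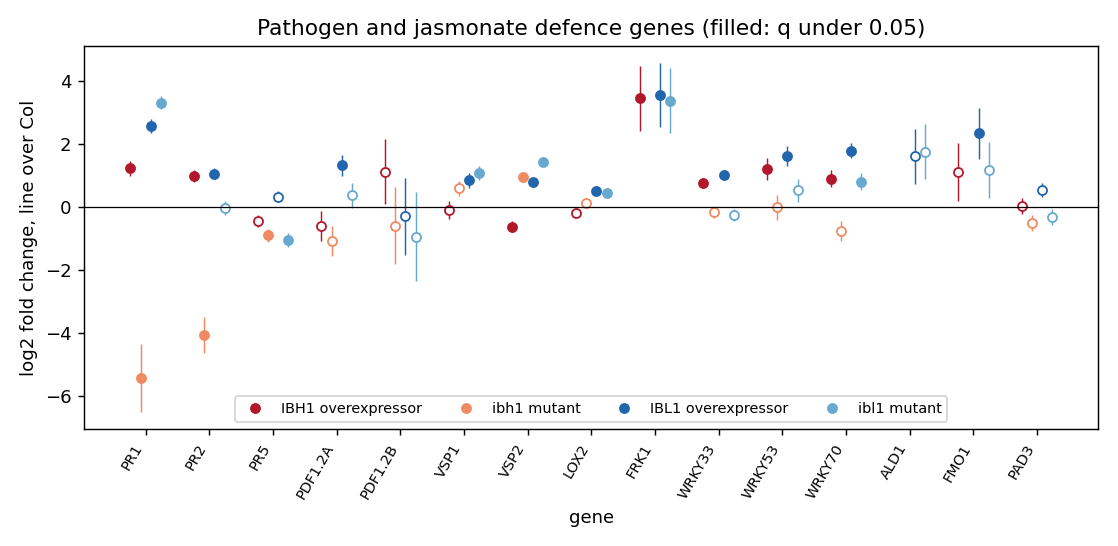
Log2 fold change over Col with its standard error (vertical axis) of the tested pathogen and jasmonate defence genes (horizontal axis) in the 4 lines (colours), filled where the authors' q was below 0.05. PR1 is at -5.41 in the ibh1 mutant and at 3.32 in the ibl1 mutant, and PR2 is at -4.06 in the ibh1 mutant.

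Opposite changes in the mutant and the overexpressor of the same gene were the smaller part of the shared calls. For IBH1, 50 genes were opposite and 235 went the same way among 20283 tested in both (27.9 and 28.6 for independent lists, 0 and 2.1 for unchanged groups). PR1 (1.23 ± 0.25 in the overexpressor, -5.41 ± 1.07 in the mutant), PR2 (1.00 ± 0.19 and -4.06 ± 0.57) and the aspartyl protease gene AT5G10760 (1.43 ± 0.35 and -2.03 ± 0.62) followed IBH1 within this pair, and the potassium transporter gene HAK5 (AT4G13420, -3.60 ± 0.85 and 1.05 ± 0.29) went against it. PR1 also rose in the ibl1 mutant (3.32 ± 0.21) and the IBL1 overexpressor, where IBH1 was not called. It therefore did not follow IBH1 over all lines. For IBL1, 78 genes were opposite and 431 went the same way among 20462 (105 and 57.0 for independent lists, 0 and 4.7 for unchanged groups). The pyrophosphatase gene PS2 (AT1G73010, 0.79 ± 0.15 and -0.86 ± 0.20), the chitinase-family gene AT2G43620 (1.00 ± 0.14 and -0.90 ± 0.20) and the small heat shock protein gene AT5G51440 (0.92 ± 0.25 and -1.15 ± 0.37, the latter call lost after centring) followed IBL1. For IBH1 the covariance was 0.0650 against 0.0459 simulated, but the Pearson (0.388 against 0.453) and Spearman correlations (0.388 against 0.423) lay below the simulated ones. For IBL1 the covariance was 0.0838 against 0.0456, the Pearson correlation 0.489 against 0.457 and the Spearman correlation 0.446 against 0.421. How much of each same-direction overlap comes from the shared control cannot be told.

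Across the 4 lines, 15 genes were called higher and 98 lower in every line among 20041 genes tested in all. The higher ones included IRT3 (log2 between 4.42 and 5.03), the nicotianamine synthase gene NAS4 (AT1G56430) and the light-signalling gene SPA3, the last pair chosen after their values were seen. The lower ones included 10 light-harvesting genes of the fixed list, PIF4, CPD, PRR7, GH3.6, GASA14 and UBQ10. All of these share the same Col value, so a Col value that is off by chance would place a gene in this set.

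**Figure D5:**
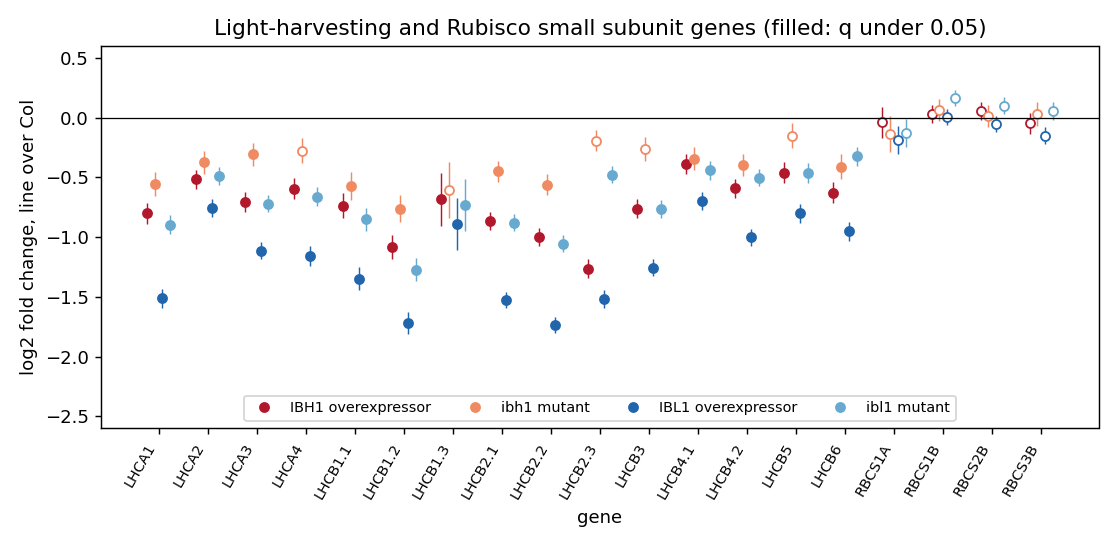
Log2 fold change over Col with its standard error (vertical axis) of 15 light-harvesting and 4 Rubisco small subunit genes (horizontal axis) in the 4 lines (colours), filled where the authors' q was below 0.05. The light-harvesting genes lie below 0 in every line and lowest in the IBL1 overexpressor (LHCB2.2 at -1.74), while none of the Rubisco genes was called.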

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

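The results below are those with the largest tested differences between 2 lines in their change from Col. The 5 for the overexpressors follow a rule fixed before the data were examined, and the 5 for the mutants were chosen only after the results had been seen. The values rest on the authors' group values, and the adjusted p is that of the difference test over all genes of a pair.

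Between the overexpressors, IBH1 differed by 7.99 ± 0.30 (IBH1 overexpressor minus IBL1 overexpressor, adjusted p 3.84e-154) and IBL1 by -6.78 ± 0.75, which are the genes put in. AT3G01345, an uncharacterised gene, differed by 7.02 ± 1.51 (adjusted p 0.00021), with 162 FPKM in the IBH1 overexpressor, 1.25 FPKM in the IBL1 overexpressor and 0.245 FPKM in Col. PRP40C differed by 5.09 (adjusted p 2.6e-08), with 9.05 FPKM in the IBH1 overexpressor, 0.266 FPKM in the IBL1 overexpressor and 7.74 FPKM in Col. RD20 differed by -4.46 ± 1.15 (adjusted p 0.00395), with 0.481, 10.6 and 3.77 FPKM in the same order. Of these lines, the insertion site of each transgene is not given in the sources used here, so its part in the changes of AT3G01345 and PRP40C was not tested.

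Between the mutants, PR1 differed by -8.73 (ibh1 minus ibl1, adjusted p 7.85e-12), with 0.454 FPKM in ibh1, 193 FPKM in ibl1 and 19.3 FPKM in Col. PR2 differed by -4.04 ± 0.61 (adjusted p 4.98e-08), with 1.12, 18.4 and 18.6 FPKM in the same order. PCR1 (AT1G14880), a cadmium resistance gene, differed by -6.99 ± 1.28 (adjusted p 5.02e-05), with 0.244, 31.0 and 17.5 FPKM. LTP4 differed by -3.85 ± 1.02 (adjusted p 0.0379) and AT4G04223, a gene without a product name, by -2.96 ± 0.66 (adjusted p 0.00265).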

How the results depend on the processing

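Each group has a single value, so no library could be left out, and p-values rest on the authors' own model of spread. No paired analysis was possible because the authors' tables give 1 value per group and none per numbered library. Depth per library is unknown, so what depth limits was not measured. At a q threshold of 0.01, 1012, 334, 1882 and 606 genes were called in the IBH1 overexpressor, ibh1 mutant, IBL1 overexpressor and ibl1 mutant, and at least 2-fold changes were called for 374, 91, 551 and 137; both settings call fewer genes by construction. Calls shared in the same direction at 0.01 were 394 (overexpressors), 142 (mutants), 103 (IBH1 pair) and 245 (IBL1 pair), with 54, 6, 27 and 39 opposite, and at 2-fold 116, 24, 16 and 48, with 1, 1, 5 and 1 opposite. With the Col error dropped as a fixed share of the summed squared errors, 3159 genes differed between the overexpressors and 502 between the mutants. A minimum FPKM of 1 kept all of these totals within 1.5 times the main ones. Centring did so for the totals of calls and of differences, though not for their split into higher and lower (IBL1 overexpressor 2221 and 769 before, 1188 and 1285 after; mutants' differences 62 and 31 before, 27 and 44 after), and was not run on the overlaps.

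Of 88 list results, 76 kept their direction and side of the threshold with a correlation of 0.05 and the other 12 lost the call, 62 were kept among random matched lists, 43 with the log2 fold change (pseudocount 0.1) and 54 with a pseudocount of 1. The lists called numbered 4 in the ibh1 mutant and 8 in the IBL1 overexpressor with a correlation of 0.05. With the log2 fold change they numbered 4, 1, 4 and 2 in the order of lines above, and 6, 1, 3 and 4 with a pseudocount of 1. The call of chloroplast-encoded genes in the IBL1 overexpressor turned from lower to higher with the log2 fold change at a pseudocount of 0.1 (adjusted p 0.0259). With a pseudocount of 1 no list of that line was called against its main direction. The cause was not tested, and neither was what the selection for poly(A) did to organelle transcripts. Keeping the 6 members ended 1 call, that of the HBI1 clade in the IBL1 overexpressor (adjusted p 0.0546). Of 332 values of named genes, 313 kept direction and call after centring and 18 lost the call.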

Other observations

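Further photosynthesis genes fell beside the light-harvesting list. Of 22 nuclear genes for photosystem subunits, a group chosen after the results had been seen, 19 were called lower in the IBH1 overexpressor, 13 in the ibh1 mutant, 21 in the IBL1 overexpressor and 15 in the ibl1 mutant, and 0 higher in any line; 12 were lower in all 4. PSAF (AT1G31330) had -0.84 ± 0.08, -0.45 ± 0.09, -0.98 ± 0.07 and -0.60 ± 0.07 in that order, and PSAD-2 (AT1G03130) -0.64 ± 0.07, -0.40 ± 0.09, -1.07 ± 0.07 and -0.66 ± 0.07.

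Some iron storage genes, also chosen after the results had been seen, were called lower. The ferritin gene FER1 (AT5G01600) had -1.52 ± 0.10, -0.92 ± 0.10, -0.45 ± 0.08 and -1.36 ± 0.09 in the same order, and AT3G25190, of the vacuolar iron transporter family, -0.72 ± 0.17, -0.87 ± 0.17, -1.34 ± 0.18 and -0.80 ± 0.17. Of 7 tested ferritin and transporter-like genes, 4, 3, 4 and 3 were called lower and 0 higher, while FER2 and FER3 were not called in any line. The gene at the ribosomal RNA locus AT2G01021 stood at 1.26e+06 FPKM in Col and had fold changes between -0.22 and 0.13 in the lines, none of them called. Other ribosomal RNA genes were called: AT2G01020 and AT3G41979, which hold the same values, had -0.34 ± 0.11 in the ibh1 mutant and 0.57 ± 0.09 in the ibl1 mutant, the plastid gene ATCG00960 was called lower in the ibh1 mutant (-1.50 ± 0.27), the IBL1 overexpressor (-1.34 ± 0.26) and the ibl1 mutant (-1.16 ± 0.26), and ATCG00920 in the IBH1 overexpressor (-0.47 ± 0.14), the ibh1 mutant (-0.65 ± 0.15) and the IBL1 overexpressor (-0.78 ± 0.13).

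The light-harvesting list lay lower in all 4 lines, and 2 explanations were weighed; the test for the Col value was written after the result had been seen, the test for time of day before. A Col value that was too high by itself would give the same level in every line. The median member was 0.649 lower in the IBL1 overexpressor than in the ibh1 mutant (-0.649, 19 of 19 members lower). This argues against Col as the whole cause in the IBL1 overexpressor, though a share due to Col may remain. The pair of lines was chosen after the values were seen, and the members are not independent. How much of the fall in the other lines is due to Col was not tested. A common shift in time of harvest would move morning against evening clock genes alike, but that difference was -0.68 ± 0.27, 0.32 ± 0.21, -0.16 ± 0.23 and -0.22 ± 0.29 in the lines (smallest -0.16). PRR7, outside both means, was called lower in all 4 lines (-0.70, -0.51, -1.60 and -1.29) and goes with such a shift, while ELF3, the other clock gene outside them, was called in none. The change of sign between lines met what the test as written took as arguing against a common shift. Weighing PRR7 was not part of that test. As the means left out a called clock gene, time of harvest stays open, and no biological explanation was tested.

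Calls in the IBL1 overexpressor leaned to higher and those in the ibl1 mutant to lower, and both tests were written before the result was seen. A single scaling factor would shift genes of every expression level alike, but over 5 equal groups of genes by FPKM the median in the IBL1 overexpressor went from 0.19 in the lowest to 0.06 in the highest (range 0.127, bootstrap interval 0.107 to 0.152). This range passed the bound that the test as written took as arguing against a single factor. A comparison with the ibh1 mutant was not part of the test as written. That mutant, whose median was not shifted, had a larger range (0.165). Such a trend therefore also arises without a shift of the median. Calls of at least 2-fold, far beyond the shifts of 0.12 and -0.07, leaned too. They were 441 higher and 110 lower in the IBL1 overexpressor and 47 and 90 in the ibl1 mutant. That split was not part of the test and was not repeated after centring, so a single factor stays open. Over 5 equal groups by gene length (start to end in the genome) the range was 0.113 in the ibl1 mutant and 0.0859 in the IBL1 overexpressor. The IBH1 overexpressor, whose calls did not lean, had 0.104 and the ibh1 mutant 0.129. Neither outcome of the test as written was met. The medians rose with length in every line, from 0.07 to 0.16 in the IBL1 overexpressor and from -0.13 to -0.02 in the ibl1 mutant. Comparing these directions was not part of that test. A trend in the same direction argues against gene length as the sole cause of opposite leans. A share due to length may remain, and no biological explanation was tested.

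IRT3 was higher in all 4 lines, and both tests were written after this had been seen. The lines stood at 11.8 FPKM or more against 0.551 FPKM in Col. The largest difference between 2 lines was 0.607 (IBL1 overexpressor minus ibl1 mutant), or 0.832 standard errors. That error (0.73) was as large as the error of 1 line against Col, so only part of the Col error was taken out. With Col at so low a level, most of the error may be Col's, and the test could hardly separate the lines. An unusual Col value alone therefore stays open, as does a change shared by the lines. Values on an iron shortage response in every line were mixed. Against it, the median of BHLH38, BHLH39, BHLH100 and BHLH101 was 0.58, 0.15, 0.01 and 0.37 in the lines (lowest 0.0138). IRT1 was also called lower in the ibl1 mutant. With it went FER1 and AT3G25190, called lower in all 4 lines, and NAS4, called higher in all 4 (1.31, 0.86, 0.91 and 0.87). Such a response therefore stays open, though these genes share the same Col value. A response in some lines also stays open. The IBH1 overexpressor, with the median of 0.58, had 2 of the 4 bHLH genes called higher, and the other lines had 0. FRO2 was called higher in the ibh1 mutant (0.70 ± 0.16) and the IBL1 overexpressor (0.58 ± 0.15). IRT1 was called higher in the IBL1 overexpressor (0.35 ± 0.10), a call lost after centring.

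A hypothesis written before its test was that the rise of SEP3 in the IBH1 overexpressor belonged to a wider rise of floral identity genes. Of 5 other genes tested, 1 was called higher (AP3, AT3G54340, at 2.53 FPKM against 0 in Col, authors' q 0.0193), while SEP4 had 0.20 ± 0.50, SOC1 -0.13 ± 0.28, AGL24 -0.30 ± 0.30 and FT 1.19 ± 0.93. At most 1 such call was what the test as written took as arguing against the hypothesis, and that was met. No allowance for genes without a test was part of it. The other 7 of the 12 listed genes, AP1, FUL, SEP1, SEP2, AG, PI and LFY, had no test at their low levels, so the values leave the hypothesis undecided. A second hypothesis, also written before its test, was that the fall of ASN1 and SEN1 in all 4 lines belonged to lower carbon starvation genes. Other genes of that list had fold changes below 0 in 4 of 10, 6 of 11, 7 of 11 and 10 of 10 cases in the lines (smallest share 40%), with 2, 1, 2 and 3 called lower and 2, 0, 1 and 0 called higher. A minority below 0 in any line was what the test as written took as arguing against the second hypothesis. The IBH1 overexpressor met that with 4 of 10, and TPS8 (0.56 ± 0.13) and BGAL4 (0.60 ± 0.12) rose there. Yet SEN5 fell in all 4 lines, and a share of 10 genes is uncertain, an allowance not in the test as written. The values therefore leave the second hypothesis undecided.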
